A study of Mus musculus with 11 samples.

How the data were processed

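Small RNA was sequenced from the livers of telomerase-knockout mice on a C57/B6 background. Per the labels' protocols, total RNA was isolated from 50 mg of liver with Trizol, treated to remove DNA, purified on a column and made into libraries with an Illumina kit that the labels call a DNA sample kit. Adapter trimming, size selection and strand are not given in the sources used here. The 11 libraries fall into 2 groups by the genotype in their titles: 5 from G4 p53+/+ mice, with short telomeres and intact p53, and 6 from G4 p53-/- mice, with short telomeres and no p53. Replicate numbers are those of the titles and run across both groups, so they pair no library of one genotype with a library of the other. All libraries carry the same date and lane 4 in their descriptions, so no sequencing batch could be told apart by lane. Each description also carries an HA number, whose meaning is not given: 580 to 584 for the p53+/+ libraries, and 406, 407, 411, 573, 587 and 588 for the p53-/- libraries. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples.

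The authors deposited read counts per mature miRNA and hairpin, assigned on mouse genome build GRCm38 per the submitters' processing notes, which also name limma. The aligner, the counter and their versions are not given in the sources used here. The authors' deposited count table had 1418 entries for 1281 mature miRNA names, because 76 names with several hairpins were listed once per hairpin, giving 137 repeats with nearly the same count. The values per library were identical to those in the table of the whole series (0 differing values). The authors also deposited a normalized table in CPM, which are counts scaled to a fixed total per library.

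For the results reported here, each mature miRNA was counted once, with the highest count over its hairpins. The copies of a name differed by up to 96.0% for miR-92a-3p, 52.4% for miR-128-3p and 11.8% for miR-466i-5p, so these counts are uncertain, and by less than 0.5% for every other name with a mean count of at least 50. Reads of near-identical miRNAs, such as miR-199a-3p and miR-199b-3p, may be counted under both names. Of the 1281 names, 470 had no read in any library and 811 were detected. Total counts per library, with each miRNA counted once, ran from 1905609 to 6682492, so that 3 counts, the upper limit that a count of 0 allows, corresponded to between 0.449 and 1.57 CPM. Intervals and limits cover counting error only, since reads were not marked by molecule. Pairs of libraries of one genotype differed by far more than sampling noise (chi-square per degree of freedom of 98.2 or more over miRNAs with at least 10 counts). Separate preparations of the same sample could exceed that noise too, so this cannot show whether any library repeats another. Each library was counted as its own sample.

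Differences between genotypes were tested with edgeR 4.0.16 in R 4.3.3: quasi-likelihood F-test, TMM scaling, filterByExpr with the genotype, and Benjamini-Hochberg adjustment over the 388 miRNAs that passed the filter, which held 99.98% of all counts. The threshold was an adjusted p of 0.05. Fold changes are p53-/- minus p53+/+ on the log2 scale, and normalised CPM are CPM after TMM scaling. On counts simulated from these libraries' means and depths, 20 times over, with 20 of 388 miRNAs changed, the test recovered 9% of 1.5-fold, 38% of 2-fold, 95% of 4-fold and 100% of 10-fold changes, and 4.35% of its calls were false. With 200 of 388 changed it recovered 26.9%, 66.5%, 98.8% and 100%, with 2.57% of calls false. The simulated spread followed the trend with level and gave no miRNA extra spread of its own. These rates may therefore be too favourable for miRNAs that vary widely between libraries. Among the real values, miR-217-5p at a log2 fold change of -4.47 was not called. Before the data were examined, 18 lists of miRNAs were fixed: 1 recalled as central to the study (miR-34a, miR-26a, miR-145a), and lists of p53-induced, Sirt1-targeting, hepatocyte, erythroid, leukocyte, endothelial, mesenchymal and stellate, epithelial and biliary, striated muscle, pancreas, neuronal, cell-cycle cluster, senescence and inflammation, fibrosis, let-7, lipid and glucose metabolism, and Dlk1-Dio3 miRNAs. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. List p-values were adjusted over the 18 lists. Camera sets a list against all other miRNAs, while fry tests whether its members move, on balance, one way.

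The miRNAs named in the text were also chosen by a rule fixed before the data were examined. It took up to 12 miRNAs in each direction past the threshold or, where fewer than 5 passed, the 5 with the smallest unadjusted p; every tested arm of miR-34a, miR-34b, miR-34c, miR-26a, miR-145a and miR-122; and up to 4 arms of each list with the smallest p. This gave 59 miRNAs, and any other is said to have been chosen after its values were seen. Library totals and shares were compared with two-sided exact permutation tests over the 462 splits of the libraries. Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom, robust edgeR, limma on the authors' CPM (pseudocount of 1), each library left out in turn, the p53-/- libraries with HA numbers above 500, and counts summed by name or hairpin. Added after seeing the data were every deposited entry, the libraries above 3000000 counts, the data without libraries 1 and 2, a correction for GC content, totals without the pancreas list and miR-122, lists without certain arms, each library left out of the GC slopes and of the cluster test, and the filter of all libraries kept where a library left out would drop a named miRNA. GC content was that of the side of the hairpin that holds the arm, for 829 of 855 hairpins matched by name to GENCODE M21 on GRCm38, which also gave the coordinates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Target genes and the messenger RNA of Trp53, the gene of p53, were not analysed here.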

Results

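MicroRNAs (miRNAs) are short RNAs that repress messenger RNAs, and each hairpin precursor can give a 5p and a 3p arm. The series measured them in liver of telomerase-knockout mice with short telomeres, a state that activates the tumour suppressor p53, to find miRNAs that depend on p53. Libraries came from 5 G4 p53+/+ and 6 G4 p53-/- samples. Total counts of the p53+/+ libraries 1 to 5 were 1965468, 1905609, 5807341, 6448820 and 4453903. Those of the p53-/- libraries 6, 7, 8, 10, 11 and 12 were 5243933, 6664274, 5963556, 5991644, 2202415 and 6682492. The means were 4116228 ± 2117043 (SD, n = 5) and 5458052 ± 1681636 (SD, n = 6), a difference of 1341824 counts that was within the spread between libraries (two-sided exact permutation p = 0.245). Each library held reads of between 535 and 637 miRNAs. The Trp53 transcript is not part of a miRNA table, so the genotype labels could not be checked on it. Mice with intact telomeres were not analysed here.

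The main comparison asked which miRNAs differ between livers with and without p53. miR-34a-5p, a direct transcriptional target of p53 that restrains the cell cycle, fell in livers without p53: its mean level was 71.9 ± 32.4 normalised CPM (SD, n = 5) in p53+/+ livers and 7.13 ± 2.95 (SD, n = 6) in p53-/- livers. The p53+/+ level was 10.1-fold the p53-/- level. The ranges did not overlap, with p53+/+ libraries between 42.4 and 120.0 CPM and p53-/- libraries between 3.90 and 12.4 CPM. The log2 fold change was -3.33 (SE 0.34, 95% interval -4.07 to -2.59), with an adjusted p of 7.07e-05 in edgeR's quasi-likelihood test, and all 6 p53-/- libraries lay below the p53+/+ median. In an exact permutation test of log2 CPM the difference was -3.23, p = 0.00216, the smallest that the 462 splits allow. It rested on counts of 129, 104, 253, 713 and 373 in p53+/+ libraries 1 to 5, and of 17, 42, 44, 66, 19 and 37 in p53-/- libraries 6, 7, 8, 10, 11 and 12.

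**Figure D1:**
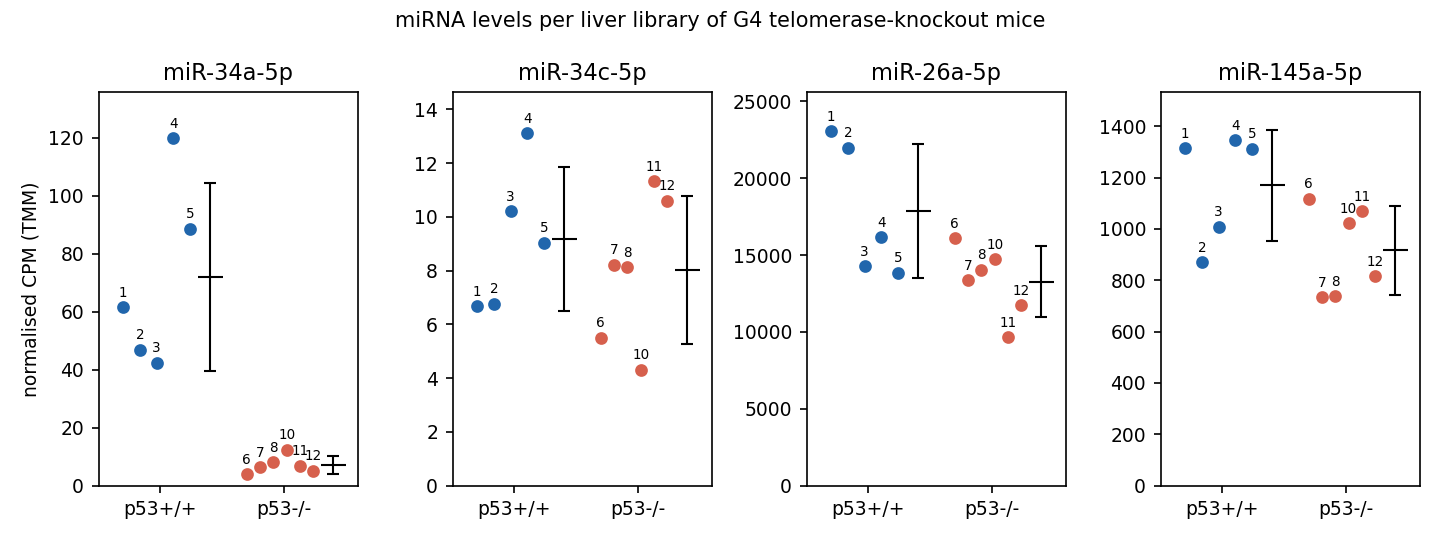
Levels of miR-34a-5p, miR-34c-5p, miR-26a-5p and miR-145a-5p in each liver library (vertical axes, normalised CPM from 0) by genotype; points are libraries with their replicate number, and bars show the mean ± SD. For miR-34a-5p the 6 p53-/- libraries sit between 3.90 and 12.4 CPM, below the 5 p53+/+ libraries at 42.4 to 120.0 CPM, while the genotypes overlap for miR-34c-5p.

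The Mir34a hairpin lies on chromosome 4 from 150068454 to 150068555 on the plus strand of GRCm38, where GENCODE M21 annotates no other gene. Its 102 nt sequence is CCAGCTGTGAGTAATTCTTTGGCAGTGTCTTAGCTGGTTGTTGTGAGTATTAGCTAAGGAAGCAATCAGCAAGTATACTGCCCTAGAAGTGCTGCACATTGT. The other arm, miR-34a-3p, had 5 reads in p53+/+ library 5 and 0 in each other library, too few to test. The related miR-34b and miR-34c, also known as p53 targets, share a separate locus on chromosome 9, with Mir34c from 51103034 to 51103110 and Mir34b from 51103562 to 51103645 on the minus strand, opposite an intron of Btg4. miR-34c-5p did not pass the test: 9.17 ± 2.68 CPM (SD, n = 5) against 8.01 ± 2.75 (SD, n = 6), a log2 fold change of -0.22 (SE 0.29, 95% interval -0.84 to 0.40, adjusted p = 0.719 in edgeR). miR-34b-3p had at most 9 reads in a library and miR-34b-5p had 0 in all, so no difference in miR-34b was detectable at this depth.

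Of the 388 miRNAs tested, 1 changed in edgeR's test: miR-34a-5p was lower without p53, and 0 were higher. At an unadjusted p under 0.05 there were 32 higher and 35 lower, 67 in all against 19.4 expected by chance, and DESeq2 called 8 higher and 9 lower, among them each miRNA named in this paragraph. The 5 miRNAs above 0 with the smallest p were miR-99b-3p (log2 fold change 0.75), miR-194-2-3p (0.49), miR-744-5p (0.58), miR-574-5p (0.62) and miR-1249-3p (0.76). All 6 p53-/- libraries were above the p53+/+ median for each of them, but none passed in edgeR, with adjusted p-values from 0.136 to 0.174. Below 0, after miR-34a-5p, came miR-374b-5p (-0.62), miR-217-5p (-4.47), miR-30c-5p (-0.51) and miR-30e-5p (-0.76), each with all 6 p53-/- libraries below the p53+/+ median and an adjusted p of 0.174 in edgeR. Lying past that median did not mean separate ranges. For miR-30e-5p, p53+/+ libraries 3 and 4 were at 1057 and 1096 CPM, while p53-/- library 12 was at 1180 CPM. The highest values were those of p53+/+ libraries 1 and 2, at 2286 and 2024 CPM, and without library 1 the log2 fold change was -0.59. For miR-217-5p the large estimate came with an SE of 1.19 and a p53+/+ SD above the mean, 40.7 ± 69.4 CPM (n = 5) against 1.78 ± 1.06 (n = 6). Differences of 1.5-fold would mostly have been missed at this sample size, since 9% of those simulated among 20 changed miRNAs were recovered.

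**Figure D2:**
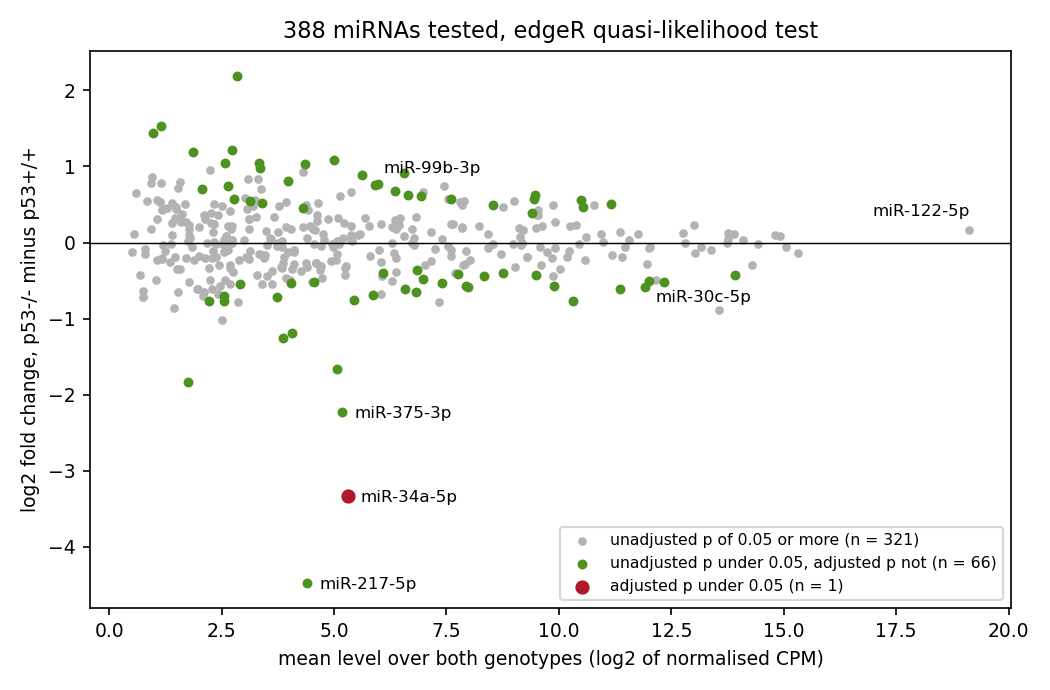
Log2 fold change, p53-/- minus p53+/+ (vertical axis), against the log2 of the mean normalised CPM over both genotypes (horizontal axis) for the 388 tested miRNAs, 1 point each. The 1 red point is miR-34a-5p at -3.33, green points passed an unadjusted p of 0.05 only, and grey points passed neither.

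The list recalled as central to the study held miR-34a, miR-26a and miR-145a, which are reported to repress sirtuins, the NAD-dependent deacetylases. All 5 tested arms of these miRNAs had values below 0 in p53-/- livers, but miR-34a-5p was the only arm to pass, both over all miRNAs and adjusted over the list alone. miR-26a-5p stood at 17871 ± 4347 CPM (SD, n = 5) and 13279.8 ± 2286 CPM (SD, n = 6), a log2 fold change of -0.43 (SE 0.18, adjusted p = 0.225 in edgeR). miR-145a-5p stood at 1170.2 ± 216.8 and 916 ± 173 CPM, or -0.35 (SE 0.18, adjusted p = 0.317 in edgeR), and miR-145a-3p at -0.40 (adjusted p = 0.208 in edgeR). The arm miR-26a-2-3p was at -0.19 (adjusted p = 0.792 in edgeR). As a set the list was lower in p53-/- livers (median -0.40, camera adjusted p = 0.000515). With an estimated correlation the adjusted p was 0.0798, and in fry it was 0.0021. Without miR-34a it was 0.0510 at the preset correlation, 0.425 with an estimated correlation and 0.116 in fry. The list was recalled from knowledge of the study and is not in the labels, so its direction and the count adjusted over the list alone are not independent evidence. Mir26a-1 lies in an intron of Ctdspl (chromosome 9, 119031796 to 119031885), Mir26a-2 overlaps an exon of Ctdsp2 (chromosome 10, 126995530 to 126995613), and Mir145a overlaps no other gene (chromosome 18, 61647825 to 61647894).

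miRNAs reported to be induced by p53 were lower as a set in p53-/- livers. Values were below 0 for 26 of the 33 tested arms (median -0.21, camera adjusted p = 0.0032). The adjusted p was 0.0798 with an estimated correlation and 0.0185 in fry. Over all miRNAs 1 arm fell in edgeR, miR-34a-5p, and adjusted over the list alone miR-194-2-3p also passed, at 0.49, opposite to the direction of the set. Other members with small p were miR-429-3p (-1.20) and miR-141-3p (-1.83), both of the miR-200 family of epithelial cells, and miR-29a-3p (-0.58), known to repress collagens; none of the 3 passed in edgeR, while DESeq2 called miR-429-3p. Without miR-34a the adjusted p of the list was 0.0255, but 0.325 with an estimated correlation and 0.116 in fry. At the preset correlation it was 0.0501 when the miR-200 family and miR-217 were left out as well. Leaving out miR-217 also took the pancreas list out of the test and the adjustment, as too few of its arms remained. With the 3 p53-/- libraries of HA numbers above 500 alone the adjusted p of the p53-induced list was 0.0663.

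The list of miRNAs reported to target Sirt1, a deacetylase that miR-34a is known to repress, shares arms with the lists above and was also lower as a set in p53-/- livers. Values were below 0 for 23 of 34 arms (median -0.19, camera adjusted p = 0.0280), and the p was 0.220 with an estimated correlation. miR-34a-5p was its 1 call over all miRNAs in edgeR, while miR-217-5p and miR-30c-5p passed adjusted over the list alone and in DESeq2 over all miRNAs. miR-217 is also on the pancreas list, whose level varied widely between the p53+/+ libraries. The adjusted p rose to 0.115, 0.0744 and 0.0759 without p53+/+ replicates 3, 4 and 5, to 0.0619 and 0.0624 without p53-/- replicates 8 and 11, and to 0.108 without miR-34a.

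Senescence and inflammation miRNAs were likewise lower in p53-/- livers as a set, with 15 of 18 arms below 0 (median -0.15, camera adjusted p = 0.0130), and the p was 0.220 with an estimated correlation. The arms with the smallest p after miR-34a-5p were miR-29a-3p (-0.58), miR-146a-5p (-0.57), a repressor of NF-kappaB signalling, and miR-29b-2-5p (-0.55), and none passed over all miRNAs or adjusted over the list alone. Without p53+/+ replicate 5 the adjusted p of the list was 0.140, and without miR-34a it was 0.108.

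miRNAs of the imprinted Dlk1-Dio3 cluster were higher as a set in p53-/- livers only in camera at the preset correlation. Of 31 tested arms, 29 had values above 0, with a median log2 fold change of 0.62. With a library left out the median ran from 0.35 without p53+/+ library 2 to 0.81 without p53-/- library 10. With all libraries the adjusted p was 0.000361 in camera at the preset correlation. With an estimated correlation it was 0.552, and fry gave an adjusted p of 0.343. No arm passed over all miRNAs or adjusted over the list alone. The 4 arms with the smallest p were miR-299a-3p (1.05), miR-485-5p (1.44), miR-299a-5p (1.53) and miR-485-3p (1.05). The 2 largest of these values came from few reads. Mean levels in p53+/+ and p53-/- livers were 1.04 and 2.87 CPM for miR-485-5p, and 1.09 and 3.36 CPM for miR-299a-5p. In a single library 3 counts stood for up to 1.57 CPM. With a library left out, the 2 arms passed the filter in 6 and 8 of 11 cases. Levels differed widely between arms. Among those with the smallest p, miR-485-3p was at 6.53 ± 3.75 CPM (SD, n = 5) and 13.6 ± 5.23 CPM (SD, n = 6), while miR-127-3p, chosen after its values were seen, was the most abundant arm, at 364.8 and 503.8 CPM on average. The arms moved together between libraries at an estimated correlation of 0.532. With the p53-/- libraries of HA numbers above 500 alone the adjusted p was 0.0507.

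**Figure D3:**
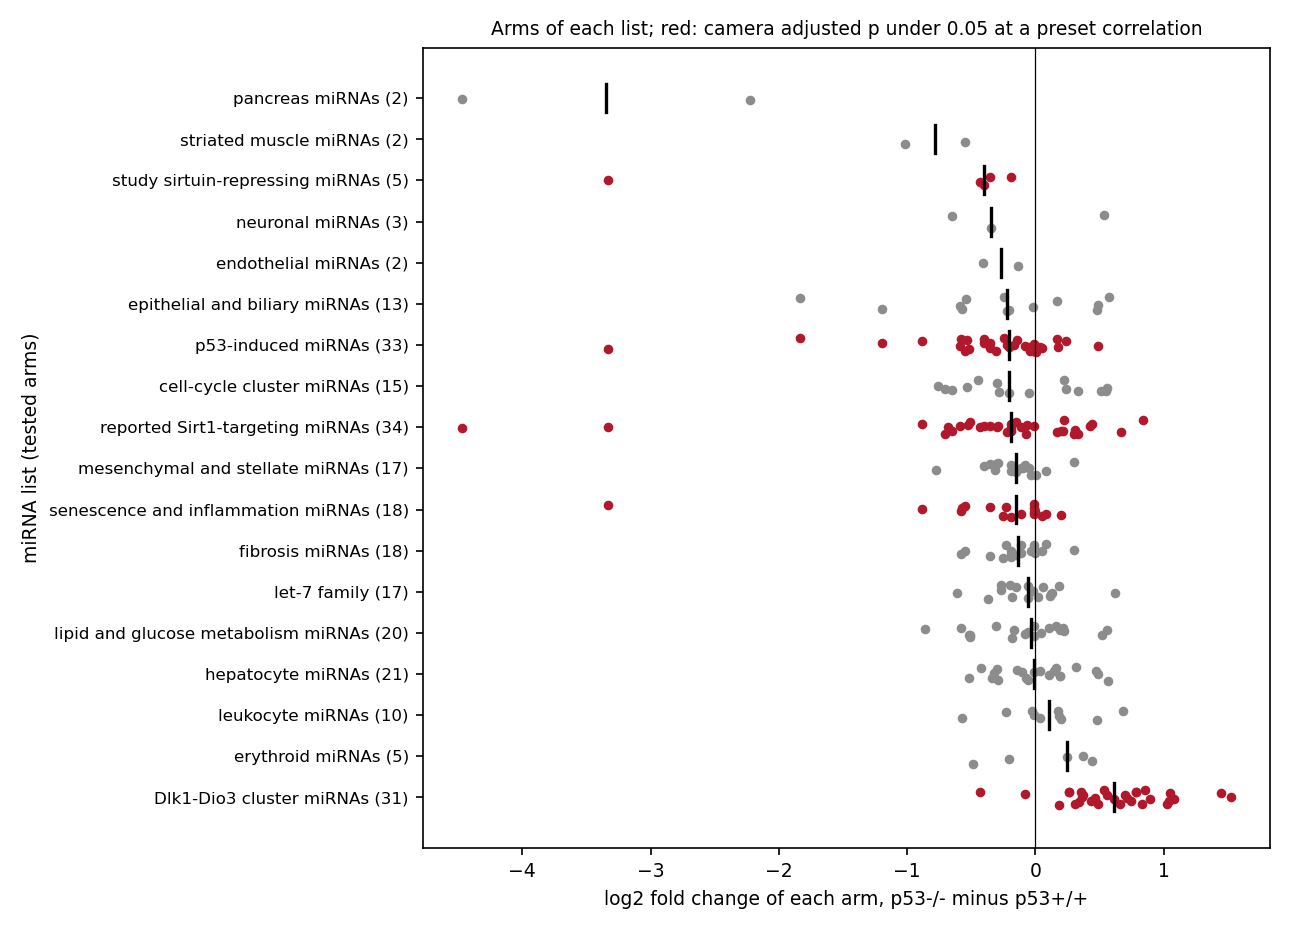
Log2 fold change, p53-/- minus p53+/+ (horizontal axis), of each tested arm (points) in the 18 miRNA lists (vertical axis, number of arms in brackets), with black ticks at the medians. Red marks the 5 lists past a camera adjusted p of 0.05 at the preset correlation, 0 of which passed with an estimated correlation; medians run from -3.35 for the pancreas list to 0.62 for the Dlk1-Dio3 list.

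Hepatocyte miRNAs did not pass the test as a set (21 arms, 11 below 0 and 10 above, median -0.01, camera adjusted p = 0.952). miR-122-5p, the most abundant miRNA of hepatocytes, made up 54.4 ± 1.95% of counts (SD, n = 5) in p53+/+ livers and 58.0 ± 4.21% (SD, n = 6) in p53-/- livers. The difference of 3.64 percentage points was within the spread between libraries (exact permutation p = 0.108). Without p53-/- replicate 12 it was 4.69 points (exact permutation p = 0.0238). Single-library shares ran from 52.4% in p53+/+ library 2 (95% Wilson interval 52.3 to 52.5%) to 64.0% in p53-/- library 6 (64.0 to 64.0%). The log2 fold change of miR-122-5p was 0.16 (SE 0.16) and that of miR-122-3p 0.19 (SE 0.13), with adjusted p-values of 0.624 and 0.516 in edgeR. Adjusted over the list alone, miR-194-2-3p (0.49) passed, while miR-194-5p was at -0.52. The count of miR-194-5p can come from Mir194-1 on chromosome 1 as well as Mir194-2 on chromosome 19, so these values do not compare the arms of a single hairpin. Other members were miR-193b-3p (0.57) and miR-365-3p (-0.42), neither of which passed.

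Lists for other cell types of the liver did not pass either. Blood miRNAs of the erythroid lineage had a median of 0.25 and a mean of 0.07 while camera put them marginally below the other miRNAs (5 arms, adjusted p = 0.986), with miR-451a at -0.49, miR-486-5p at 0.37, miR-486-3p at 0.25 and miR-144-3p at 0.44. Without p53-/- library 7, miR-144-3p fell below the filter and the median of the other arms was -0.26, with miR-486-5p at 0.18 and miR-486-3p at -0.09. With the filter of all libraries kept, miR-144-3p was at 0.02 there. Leukocyte miRNAs had a median of 0.11 (10 arms, adjusted p = 0.496), with the lymphocyte miRNA miR-150-5p, called by DESeq2 only, at 0.68, miR-146a-5p at -0.57, miR-342-5p at 0.48 and the myeloid miR-223-3p at -0.23. With each library left out, the leukocyte median turned sign in 3 of 11 cases. It ran from -0.06 without p53+/+ library 4 to 0.28 without p53+/+ library 5. The endothelial miR-126-5p and miR-126-3p were at -0.40 and -0.13 (adjusted p = 0.366 for the list). Mesenchymal and stellate miRNAs had 14 of 17 arms below 0 (median -0.15, adjusted p = 0.168), with miR-99a-3p at -0.77 and miR-214-3p at 0.30. Epithelial and biliary miRNAs had 9 of 13 arms below 0 (median -0.22, adjusted p = 0.467), with miR-31-5p at -0.57 and miR-200a-3p at -0.59 beside the miR-429-3p and miR-141-3p values above. The median of that list was 0.14 without p53+/+ library 3 and -0.43 without p53-/- library 11. For striated muscle the 2 tested arms, miR-133a-3p (-1.02) and miR-1a-3p (-0.55), gave an adjusted p of 0.496, and without p53+/+ library 4 they were at -0.50 and 0.03. For the neuronal list miR-9-5p (-0.65), miR-128-3p (0.53) and miR-137-3p (-0.34) also gave 0.496. The value of miR-128-3p rested on p53-/- library 6, without which it was -0.03, and its count is uncertain because its hairpins were given different counts.

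Pancreas miRNAs were the most uneven between libraries. miR-217-5p, abundant in acinar cells of the pancreas, reached 164 CPM in p53+/+ library 5, 22.1 in library 2 and 17.1 in library 3, but 0 in library 1 and 0.505 in library 4, and at most 2.69 in any p53-/- library. miR-375-3p, abundant in pancreatic islets, reached 178 CPM in library 5, 56.3 in library 3 and 43.3 in library 2, against 2.86 in library 1 and 15.8 in library 4, and at most 23.2 in a p53-/- library. Their log2 fold changes were -4.47 and -2.22, but -2.46 and -1.22 without p53+/+ library 5. Neither passed over all miRNAs (adjusted p = 0.174 for both in edgeR), though DESeq2 called miR-217-5p, and both passed adjusted over the list alone. As a set these 2 arms gave a camera adjusted p of 0.237. The Mir217, Mir216a and Mir216b hairpins lie together on chromosome 11 between 28746191 and 28763835, the first 2 in an intron of the long noncoding RNA Gm12082, and Mir375 lies on chromosome 1 from 74900658 to 74900721.

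**Figure D4:**
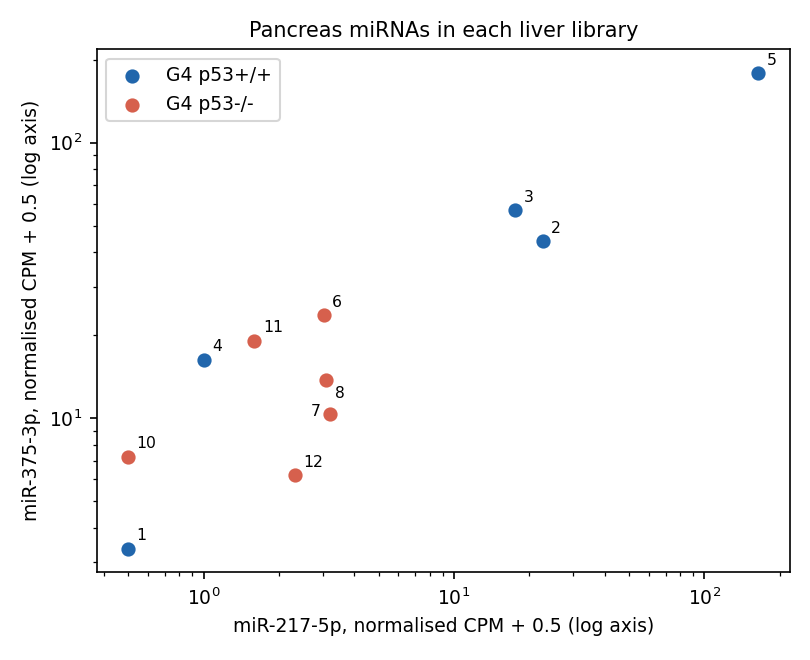
Level of miR-375-3p (vertical log axis) against miR-217-5p (horizontal log axis), both in normalised CPM plus 0.5, in each of the 11 liver libraries, labelled by replicate number and coloured by genotype. p53+/+ library 5 is highest for both, at 164 and 178 CPM, while p53+/+ library 1 is at 0 and 2.86 CPM.

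The remaining lists covered growth, fibrosis and metabolism, and none passed. The cell-cycle clusters around miR-17 and miR-106b had 9 of 15 arms below 0 (median -0.20, camera adjusted p = 0.279), led by miR-17-5p (-0.53, called by DESeq2 only), miR-93-3p (-0.71), miR-19b-3p (-0.76) and miR-20a-5p (-0.45). Fibrosis miRNAs had 15 of 18 arms below 0 (median -0.13, adjusted p = 0.208), with miR-29c-3p at -0.35. The let-7 family had 10 of 17 below 0 (median -0.06, adjusted p = 0.718), with let-7e-5p at 0.62 (0.38 without p53-/- library 6), miR-98-5p at -0.37, let-7i-3p at -0.61 (-0.18 without p53+/+ library 2) and let-7c-2-3p at -0.27. Lipid and glucose metabolism miRNAs had 12 of 20 below 0 (median -0.03, adjusted p = 0.478), with miR-27a-3p at -0.51 and miR-335-3p at -0.52. The highest values of miR-27a-3p were those of p53+/+ libraries 1 and 2, and without library 1 its log2 fold change was -0.28. Its levels in p53+/+ libraries 3, 4 and 5 were 66.7, 74.0 and 53.5 CPM, within the p53-/- range of 44.2 to 77.4 CPM.

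Libraries within a genotype also differed. p53+/+ libraries 1 and 2, the shallowest of that genotype, stood apart on the first principal component (26.9% of the variance) at -10.5 and -13.0, where the others lay between -0.77 and 5.97. p53-/- library 6 stood apart on the second (16.9%). Without libraries 1 and 2, miR-34a-5p was still the 1 miRNA called, at -3.50. Then 8 lists passed in place of 5 at the preset correlation, but 0 with an estimated correlation (smallest adjusted p = 0.223). In fry 0 passed, in place of 4 with all libraries. At the preset correlation the lists past the threshold with all libraries all passed, with adjusted p-values of 0.0017 for the study, p53-induced and Sirt1 lists, 0.0176 for senescence and 0.0216 for Dlk1-Dio3, and the mesenchymal (median -0.30), pancreas (-3.83) and fibrosis (-0.18) lists were added. The medians of the cell-cycle and let-7 lists turned, to 0.05 (7 arms below 0 and 8 above) and 0.06 (5 below and 12 above), and neither passed. In the 3 p53-/- libraries of HA numbers above 500 against all p53+/+ libraries, miR-34a-5p was at -3.16 (adjusted p = 0.0155 in edgeR).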

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

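The test of miR-34a-5p by library depth was chosen only after the result was seen, as were the relations of miR-141-3p and miR-429-3p with miR-217-5p and the GC slopes with each library left out; the other tests of this part were set before their results. A single library lay far from the rest of its genotype in 10 of the sets of values examined (59 named miRNAs, the library total and the miR-122-5p share, each by genotype), where chance gives about 6.1. Among p53+/+ libraries, miR-99b-3p was 36.1 CPM in library 2 (the others 44.8 to 48.1), miR-374b-5p was 154.5 CPM in library 1 (101.3 to 111.9), and miR-451a was 209 CPM in library 4 (119.2 to 138.4). Among p53-/- libraries, library 6 had 620 CPM of miR-744-5p (830 to 945) and 696 CPM of miR-128-3p (133.7 to 202.1). Library 10 had 0 CPM of miR-217-5p (1.10 to 2.69), 0.375 CPM of miR-485-5p (2.23 to 4.63) and 4.31 CPM of miR-485-3p (13.1 to 19.9). Library 11 had 74.5 CPM of miR-98-5p (102 to 111) and the lowest total of its genotype, 2202415 counts (5243933 to 6682492).

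The fall of miR-34a-5p was weighed against chance, depth and GC content. Of 100 splits of the libraries into groups of 5 and 6, the real one included, 3 gave at least the 1 miRNA called between genotypes. The 2 others gave 2 each, along no labelled division: miR-3107-5p and miR-486-5p in the first, miR-5105 and miR-6243 in the second. The second had the shallow libraries 1, 2 and 11 in the same group. No other split gave as small a p in edgeR's test (2.75e-05 at best, against 1.82e-07). By number of calls, 3 of 100 splits makes chance unlikely but does not exclude it. In the 8 libraries above 3000000 counts the log2 fold change was -3.53, and after a GC correction per library it was -3.26, both past the threshold, which argues against depth or GC content as the whole cause. Loss of p53 is a candidate explanation, as a hypothesis, since miR-34a is a known p53 target. The animals' age and litter were not tested and stay open.

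The pancreas miRNAs were weighed as stray tissue against genotype. If some liver samples held pancreas, miR-375-3p should follow miR-217-5p although the hairpins lie on different chromosomes, and it did: across the 11 libraries Spearman's rho was 0.747 (permutation p = 0.0109, adjusted 0.0435) and Pearson's r 0.910 (permutation p = 0.00021, adjusted 0.00168, over 8 relations tested). Without libraries 5 and 2, farthest from the median, r was 0.782 and rho 0.552, but within the 6 p53-/- libraries r was 0.406 (exact permutation p = 0.481, adjusted 0.816) and rho 0.200 (exact permutation p = 0.714, adjusted 0.816), so the relation may rest on the p53+/+ libraries. The mean log2 level of miR-216a-5p, miR-216b-5p and miR-217-5p did not separate the genotypes (exact permutation p = 0.154, with 2 p53+/+ libraries below the p53-/- median and 0 p53-/- libraries above the p53+/+ median), which keeps genotype open. miR-141-3p and miR-429-3p of the epithelial list did not follow miR-217-5p (rho -0.31 and 0.04, permutation p = 0.359 and 0.907, adjusted 0.816 and 0.907; r -0.23 and 0.16, permutation p = 0.510 and 0.643, both adjusted 0.816; r -0.30 and 0.04 without libraries 5 and 2).

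Log2 fold changes rose with GC content across the miRNAs with a GC value (r 0.184, permutation p = 0.00031, and rho 0.199, permutation p = 9e-05, adjusted 0.00031 and 0.00018 over 2 relations), although miRNAs are not independent replicates. Their median was -0.10 where GC content was 43.9% or less and 0.21 where it was 57.1% or more. For each library, log2 levels were taken as deviations from the mean over all libraries, so the signs of the slopes are relative to that mean. The slope of these deviations on GC content, per 10 percentage points, was -0.06 ± 0.06 (SD, n = 5) in p53+/+ and 0.05 ± 0.09 (SD, n = 6) in p53-/- libraries (exact permutation p = 0.0433). The ranges overlapped through p53-/- library 6 alone. Without it they did not (exact permutation p = 0.00794), while 9 of the 10 other omissions gave an exact permutation p above 0.05. A library bias in GC and a difference tied to genotype can therefore not be told apart. The slope of the fold changes in the 8 deeper libraries was 0.636 of that in all, which leaves a part for depth open. The correction for GC content left miR-34a-5p as the 1 call.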

How the results depend on the processing

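The settings with every deposited entry, only the libraries above 3000000 counts, no libraries 1 and 2, the GC correction, no pancreas list and miR-122, and lists without certain arms were chosen after seeing the data; the rest were fixed beforehand. miR-34a-5p was called in every setting and was the only call in all but DESeq2, with log2 fold changes from -3.58 to -3.12 and adjusted p-values up to 0.0155 where it was tested as an arm. DESeq2 called 17 miRNAs, 8 higher and 9 lower. edgeR called 1 with no filter (811 miRNAs tested), with 10 CPM in 5 libraries (248 tested) and with DESeq2 size factors (388 tested). This argues against the filter or the scaling alone as the source of the added calls, and what in the test makes the difference was not tested. The number of lists past the threshold at the preset correlation, 5 at first, was between 3 and 7 when a library was left out, 3 with the p53-/- libraries of HA numbers above 500, 10 with the libraries above 3000000 counts, 8 without libraries 1 and 2, 2 without miR-34a, and 1, the Dlk1-Dio3 list, without miR-34a, the miR-200 family and miR-217; dropping arms or libraries changes what is tested, and no further cause was tested. Among the settings with a single library left out, the lowest number was 3, without p53+/+ replicate 5. With an estimated correlation 0 lists passed at first. The study list passed with library totals as the scaling, on the authors' CPM and without p53-/- replicate 10. The p53-induced list passed without that replicate and with the arms of a hairpin summed. In fry 4 lists passed at first, and 5 with the p53-/- libraries of HA numbers above 500. With upper-quartile scaling, library totals or the authors' CPM 1 passed in fry, and with the libraries above 3000000 counts 0. The difference in miR-122-5p share was 2.45 to 4.69 percentage points with a library left out (4.69 without p53-/- replicate 12, exact permutation p = 0.0238), and that in library totals 789169 to 1992952 counts. Over the named miRNAs, 1588 of 1615 values kept direction and side of the threshold, 12 passed under DESeq2 alone, and 15 uncalled values changed sign. Of 534 values of the lists, 15 no longer passed, 12 newly passed, 20 changed direction without a call, and the others kept both. With a single library left out, 3 of 59 named miRNAs (miR-1a-3p, miR-128-3p and miR-486-3p) and the medians of 5 of 18 lists turned sign, none of them called. Depth limits miR-34a-3p and miR-34b, which were near 0.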

Other observations

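The tests of list means and of genomic clusters in this part were chosen only after the lists' results were seen. The mean log2 level over each list's arms gave a value per library, compared between genotypes with exact permutation tests adjusted over 18 lists. The study list (difference -0.94), the p53-induced list (-0.31) and the senescence list (-0.34) each had the smallest exact p the splits allow, 0.00216 (adjusted 0.0130), with 0 of 6 p53-/- libraries above the p53+/+ median. Without miR-34a the differences were -0.36, -0.22 and -0.17 (exact p = 0.0173, 0.0152 and 0.0541), and none passed the adjustment (0.156, 0.156 and 0.325). The Sirt1 list did not pass (difference -0.23, exact p = 0.0216, adjusted 0.0974), nor did it without miR-34a (-0.14, exact p = 0.141, adjusted 0.354). The Dlk1-Dio3 arms rose and fell together from library to library: their mean log2 level was 2.65 ± 0.58 (SD, n = 5) in p53+/+ and 3.23 ± 0.70 (SD, n = 6) in p53-/- livers (exact p = 0.184, adjusted 0.354), with 5 of 6 p53-/- libraries above the p53+/+ median and library 10 the exception at 2.04.

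Some miRNAs lay far from the median in particular libraries, and all but miR-128-3p were chosen after their values were seen. p53-/- library 6 stood 2.39 above the median of the other 10 libraries on the log2 scale for miR-181b-5p and 1.95 for miR-128-3p, and was at -2.85 for miR-1948-5p and -2.11 for miR-455-3p. p53+/+ library 2 was 1.94 above for miR-22-3p and at -1.77 for miR-127-3p of the Dlk1-Dio3 cluster, but neither was particular to it. For miR-22-3p p53+/+ library 1 was also high, at 20589 CPM beside 33766 CPM in library 2, and the next was p53-/- library 12 at 11218 CPM. For miR-127-3p p53-/- libraries 6 and 10 were at -1.89 and -1.02. No explanation of these values was tested.

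The hairpins of miR-99b, let-7e and miR-125a lie within 10000 bp of each other on chromosome 17, from 17830188 to 17830879, inside Spaca6. Of 26 such clusters with at least 3 tested arms, this was the 1 that passed fry at an adjusted p of 0.05: all 6 arms were above 0 (median 0.57, SD 0.29 over arms, adjusted p = 0.0457). With each library left out in turn, a setting also added after the result was seen, it passed in 2 of 11 cases, and without p53-/- library 6, the highest for let-7e-5p, the median was 0.46 (adjusted p = 0.0756). A shared change of the cluster in p53-/- livers is a possible explanation, as a hypothesis. The values that would exclude it were set, and then changed, after the result was seen: at first an adjusted p above 0.05 after the GC correction was to count against it, then only a median of 0 or below. After the GC correction 5 of 6 arms were above 0, the median over arms was 0.39 (SD 0.29) and the adjusted p 0.274. By the first rule the hypothesis failed, and by the second it stayed open. The call ended with a smaller fold at the same spread, and a change of the cluster cannot be told apart from the trend with GC content.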
